A study of Homo sapiens with 33 samples.

How the data were processed

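RNA was measured in 33 libraries from formalin-fixed, paraffin-embedded (FFPE) colon biopsies, described in the labels as mucosal tissue. The labels assigned 18 libraries to graft-versus-host disease (GVHD), in which donor immune cells attack the tissues of a transplant recipient, and 15 to no GVHD. Per the labels' protocols, RNA was isolated with a kit for FFPE material and libraries were made with an exome-capture RNA kit, which enriches for coding transcripts. Such RNA is fragmented, so values rest on short fragments and on the capture probes. Other biopsies that the series describes were not analysed here.

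The deposited values are FPKM per gene (fragments scaled by gene length and by the library's total), in a table of 48162 rows made by the authors. Per the submitters' processing notes, HISAT2 2.1.0, featureCounts 1.6.4, DESeq2 version 2 and edgeR 3.16.5 were used, with no role, order or setting given. The genome build was not given in the sources used here. It is not GRCh38: of 45342 rows whose identifier is in GENCODE v29, 0.66% have the same start, and the largest chromosome 1 coordinate, 249231242, lies beyond the last chromosome 1 gene end of that annotation, 248937043. Coordinates below are those of the deposited table. Whether reads were counted by strand was not given in the sources used here, so reads of overlapping or near-identical genes cannot be separated here.

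FPKM divides by the total of a library, so a few abundant genes that differ between groups shift all others. Multiplied by gene length, the deposited FPKM values were whole multiples of one step in each library, 100% of them within 0.01 read. The recovered reads totalled 12163000 to 29667000 per library. One FPKM for a gene of 1 kb therefore stood for 12.2 reads in the shallowest library and 29.7 in the deepest. No pair of libraries agreed within sampling noise: the smallest chi-square per gene between any 2 libraries was 51.17.

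The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust settings) on log2(FPKM + 1), with no covariate, since the labels name no batch or pairing. Genes at FPKM 1 or more in at least 15 libraries were tested, 13835 in all. P-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates changes of low genes, and are given with their standard error. Group levels are mean FPKM ± SD over 18 GVHD and 15 no GVHD libraries.

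The test, the filter, 41 gene lists, the naming rule and most alternatives were fixed before the data were examined. Lists with at least 3 tested members, 37 of them, were tested with camera (preset correlation 0.01). Each also had a score per library, the mean log2(FPKM + 1) of its tested members, compared by a two-sided permutation test with 100000 resamples and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Of 528 listed genes, 525 were matched to the table by identifier or symbol. Genes were named if they were among the 12 largest differences in each direction past the threshold with mean FPKM of 1 or more in a group, or among up to 4 members of a list with the smallest p. Immunoglobulin and T cell receptor variable segments, pseudogenes by the gene type in the deposited table, genes that reveal sex and rows with only a clone name were left out of naming. Some list members are not reported here by name.

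Alternatives changed the pseudocount, the filter, the scaling, the weights, the variance model and the covariates, or left out each library in turn. Alternatives chosen after seeing the data were limma voom on the recovered reads, omission of 2 GVHD libraries that stood apart on the first principal component (23.3% of variance), the mitochondrial share as covariate, the distal colon position score as covariate, and that omission together with the pan-epithelial covariate.

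The test was tested on simulated data for this comparison, with reads drawn for the real genes and 100 genes changed by 2-fold and 100 by 4-fold. Over 13910 simulated genes past the filter, 71% of the 2-fold and 87% of the 4-fold changes were recovered. Of 165 calls, 7 were unchanged genes. The simulated genes were independent, so this does not test how correlated genes behave. Their spread between libraries was that of the no GVHD libraries in both groups, so a wider spread in GVHD was not tested either.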

Results

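Gene expression was measured in 33 libraries from paraffin-embedded colon biopsies, 18 from the GVHD group and 15 from the group without GVHD. Depth was 12163000 to 29667000 reads per library. It did not differ detectably between the groups by a two-sided permutation test (adjusted p = 0.478). The labels do not say that each library came from a separate patient, so p-values measure only the spread between these samples. The comparison addressed which transcripts of the colon mucosa differ in level with GVHD. Groups were taken from the disease state label alone. Transplant history and treatment entered no comparison, so a difference between the groups cannot be credited to GVHD alone.

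The scores of macrophage, cytotoxic lymphocyte and interferon gamma response genes were higher in GVHD, and those of absorptive colonocyte, drug handling, tight junction and plasma cell genes were lower, each past the permutation test. Without GVHD libraries 17 and 18, which stood apart, the colonocyte and plasma cell scores no longer passed (permutation adjusted p = 0.0804 for each), the colonocyte difference going from -0.81 to -0.52 and the plasma cell one from -1.36 to -1.26. None of these 7 lists kept its camera call with an estimated correlation (adjusted p = 0.335 to 0.373), and 1 of 10 plasma cell, 3 of 15 drug handling and 3 of 12 tight junction genes passed singly. CD163, a scavenger receptor of macrophages, averaged 58.6 ± 31.9 FPKM in GVHD and 12.5 ± 3.76 without. GZMB, a protease of cytotoxic granules, averaged 10.6 ± 9.83 and 1.07 ± 1.08 FPKM. ABCB1, an efflux pump of the epithelium, averaged 25.2 ± 5.64 FPKM in GVHD and 51.1 ± 21.8 without, and all 18 GVHD libraries lay below the no GVHD median. Of 13835 genes tested with limma, 1096 were higher and 557 lower at an adjusted p under 0.05, and 103 and 91 of these by 2-fold or more.

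The largest rise was that of CHI3L1, a secreted chitinase-like protein of inflamed mucosa (ENSG00000133048, chromosome 1, start 203148059, end 203155877). Its log2 difference was 2.92 ± 0.62 (limma adjusted p = 0.0056). Its FPKM was 55.9 ± 143 in GVHD and 0.411 ± 0.252 without, so a few libraries set the GVHD mean, yet 17 of 18 GVHD libraries lay above the no GVHD median. FCGR3A, an Fc receptor of NK cells and macrophages (ENSG00000203747, chromosome 1, start 161511549, end 161600917), rose by 2.35 ± 0.33 (limma adjusted p = 0.000131). It has a near-identical neighbouring copy, FCGR3B, so its reads are uncertain. SPINK4, a goblet cell protease inhibitor, rose by 2.17 ± 0.63 and REG4, a secreted lectin of the epithelium, by 1.89 ± 0.47. SRPX2 rose by 1.96 ± 0.29, with all 18 GVHD libraries above the no GVHD median. KIAA1199, which takes part in hyaluronan breakdown, rose by 1.90 ± 0.56 and NRG1, an ERBB ligand, by 1.78 ± 0.51. KIAA1199 averaged 29.7 ± 70.4 FPKM in GVHD and 1.37 ± 1.11 without, and NRG1 99.5 ± 147 and 12.4 ± 5.95. For both genes the SD in GVHD exceeded the mean. Of 18 GVHD libraries, 16 lay above the no GVHD median for KIAA1199 and 14 for NRG1.

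Among named genes the largest falls included CDHR1 (ENSG00000148600, chromosome 10, start 85954410, end 85979377), with a log2 difference of -2.13 ± 0.48 (limma adjusted p = 0.00734). SLC6A19, a neutral amino acid transporter, differed by -2.09 ± 0.39 and averaged 3.83 ± 8.38 FPKM in GVHD against 14.6 ± 10.95. PCK1, an enzyme of gluconeogenesis, differed by -1.91 ± 0.47, LGALS2 by -1.88 ± 0.37 and CHP2 by -1.85 ± 0.36. CKB, a creatine kinase, differed by -1.76 ± 0.49, and CD177 by -1.73 ± 0.42. NXPE1, NXPE4 and C21orf88 differed by -1.69 ± 0.52, -1.66 ± 0.52 and -1.60 ± 0.39. IGHG3, an immunoglobulin constant gene that shares sequence with related genes, differed by -2.08 ± 0.66.

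**Figure D1:**
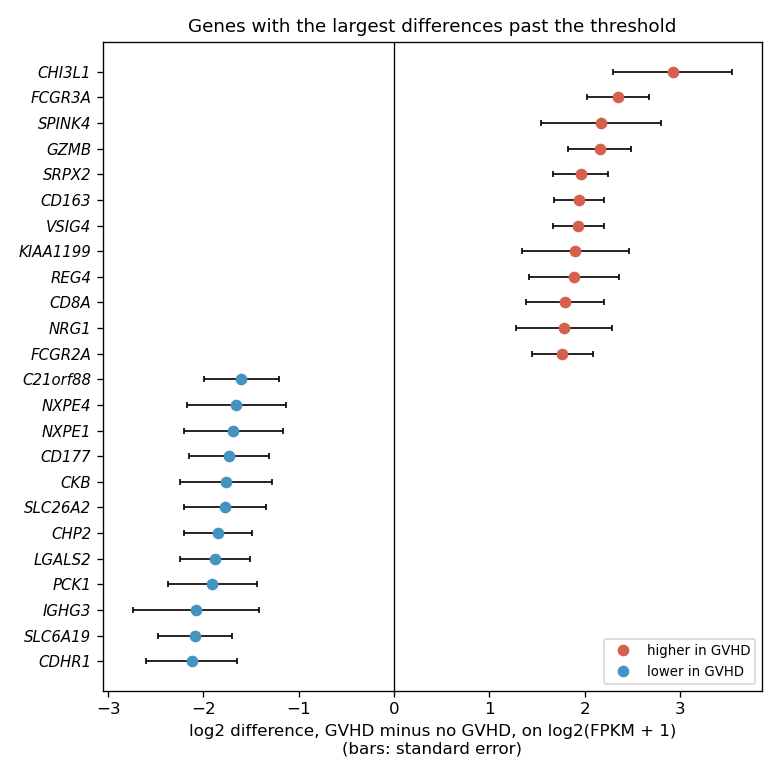
Log2 difference between GVHD (n = 18) and no GVHD (n = 15) libraries on the log2(FPKM + 1) scale for 12 genes in each direction, the largest differences left after variable segments, pseudogenes and the other exclusions of the naming rule, with standard errors as bars. Of the genes shown, CHI3L1, at 2.92, lies farthest to the right, and CDHR1, at -2.13, farthest to the left.

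Of 13 tested monocyte and macrophage genes, 11 rose and none fell, also 11 when adjusted over the list alone. The 2 that did not pass, given here outside the naming rule, were CD14 and CSF1R. CD14 differed by 0.053 ± 0.26 (limma adjusted p = 0.917) and CSF1R by 0.413 ± 0.216 (limma adjusted p = 0.198). CD163 differed by 1.94 ± 0.26, VSIG4 by 1.93 ± 0.27, the scavenger receptor gene MSR1 by 1.23 ± 0.22 and the Fc receptor gene FCGR2A by 1.77 ± 0.32. The list score was higher in GVHD by 1.13 ± 0.22 (permutation adjusted p = 0.00148), with 16 of 18 GVHD libraries above the no GVHD median. The camera call was lost with an estimated correlation, at an adjusted p = 0.335.

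Of 15 listed cytotoxic lymphocyte genes, 9 were tested and 5 rose, and 7 when adjusted over the list alone. Besides GZMB (2.16 ± 0.33), these included CD8A (1.79 ± 0.41), the pore-forming protein gene PRF1 (1.48 ± 0.32) and GZMH (1.16 ± 0.29). The score difference was 1.07 ± 0.25 (permutation adjusted p = 0.00342; adjusted p = 0.349 with an estimated correlation). Of 12 listed regulatory T cell and checkpoint genes, 5 were tested, FOXP3 and CTLA4 not among them, so the list does not show whether regulatory T cells rose. Of the 5 tested genes, 4 rose, and 4 when adjusted over the list alone. These were IL2RA, HAVCR2, LAG3 and IL10, and the score difference was 0.85 ± 0.15 (permutation adjusted p = 0.00037, the smallest these resamples can give before adjustment being 1e-05; adjusted p = 0.335 with an estimated correlation). None of 12 T cell genes passed over all genes, and 7 were higher when adjusted over the list alone. The T cell score difference of 0.69 ± 0.30 missed the threshold (permutation adjusted p = 0.0565; adjusted p = 0.48 with an estimated correlation).

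Of 16 interferon gamma response genes, 8 rose, and 12 when adjusted over the list alone. GBP1 differed by 1.33 ± 0.32 and GBP5 by 1.44 ± 0.36. The score difference was 0.78 ± 0.24 (permutation adjusted p = 0.0136; adjusted p = 0.373 with an estimated correlation). The type I interferon list had no call among 16 genes, nor when adjusted over the list alone (score difference 0.35 ± 0.31, permutation adjusted p = 0.313). Its score was 4.71 and 5.01 in no GVHD libraries 1 and 11, against a no GVHD mean of 2.53 ± 1.01. It lay above the no GVHD median in 15 GVHD libraries and below it in 3. The score difference with both of these no GVHD libraries left out was not tested, so a rise of type I interferon genes is not excluded. The 10 MHC class II genes had no call either (0.19 ± 0.28, permutation adjusted p = 0.585). Of 18 listed inflammatory cytokine and chemokine genes, 8 were tested and 5 rose, and 5 when adjusted over the list alone. They included CXCL1 at 1.29 ± 0.28 and CCL4 at 1.29 ± 0.34, whose reads can be shared with a near-identical copy. That score differed by 0.68 ± 0.23 (permutation adjusted p = 0.0261; adjusted p = 0.373 with an estimated correlation). In the neutrophil list, 3 of 14 genes were tested and CSF3R, a cytokine receptor also made by monocytes, rose, with 2 higher when adjusted over the list alone (score 0.72 ± 0.20, permutation adjusted p = 0.00893, camera adjusted p = 0.355 with an estimated correlation).

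The plasma cell score lay lower in GVHD, though not every gene of the list did. Of 10 tested genes, TNFRSF17, a receptor of plasma cells, passed over all genes (-0.86 ± 0.26), and 7 when adjusted over the list alone. The score difference was -1.36 ± 0.56 (permutation adjusted p = 0.043; adjusted p = 0.355 with an estimated correlation), and -1.26 ± 0.57 without GVHD libraries 17 and 18 (permutation adjusted p = 0.0804). Immunoglobulin genes held 0.931 ± 1.09% of summed FPKM in GVHD and 5.06 ± 5.05% without (permutation adjusted p = 0.00368), and this share moves with every FPKM value through the library total.

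Of 17 absorptive colonocyte genes, 5 fell and none rose, and 10 when adjusted over the list alone. The sulfate transporter gene SLC26A2 differed by -1.78 ± 0.43, GUCA2B, a guanylate cyclase activator, by -1.33 ± 0.36, the carbonic anhydrase gene CA4 by -1.27 ± 0.37 and CEACAM7 by -1.36 ± 0.40. The score difference was -0.81 ± 0.30 (permutation adjusted p = 0.0322; adjusted p = 0.349 with an estimated correlation), and -0.52 ± 0.24 without GVHD libraries 17 and 18 (permutation adjusted p = 0.0804). In these the pan-epithelial score was 3.50 and 3.52, against a no GVHD mean of 6.31 ± 0.396, and the fibroblast and matrix score 7.28 and 7.42, against 5.21 ± 0.45. The pan-epithelial score also lay lower, by -0.47 ± 0.24, without passing the test (permutation adjusted p = 0.125; adjusted p = 0.373 with an estimated correlation), and was -0.18 ± 0.14 without these 2 libraries. Of its 15 genes 1, ELF3, fell, also 1 when adjusted over the list alone. Of 15 drug and bile acid handling genes, 3 fell, and 4 when adjusted over the list alone. ABCB1 differed by -0.91 ± 0.16, UGT2A3 by -1.59 ± 0.33, and the score by -0.55 ± 0.18 (permutation adjusted p = 0.0167, camera adjusted p = 0.335 with an estimated correlation). The drug handling score difference was -0.368 ± 0.139 without GVHD libraries 17 and 18 (permutation adjusted p = 0.039). With the pan-epithelial covariate it was -0.268 ± 0.117. Of 12 tight junction genes, CLDN8, CLDN4 and OCLN fell, and 6 genes when adjusted over the list alone (score -0.44 ± 0.13, permutation adjusted p = 0.00893, camera adjusted p = 0.335 with an estimated correlation). The tight junction score difference was -0.300 ± 0.096 without GVHD libraries 17 and 18 (permutation adjusted p = 0.0152). With the pan-epithelial covariate it was -0.206 ± 0.058.

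Of 21 genes known to be lowered in inflamed bowel mucosa, 11 fell, and 17 when adjusted over the list alone. They included TRPM6, a magnesium channel gene, at -1.60 ± 0.37, and the list overlaps those of colonocytes and drug handling. Its score differed by -1.16 ± 0.26 (permutation adjusted p = 0.00173; adjusted p = 0.335 with an estimated correlation). Of 26 listed genes known to be raised there, 12 were tested. The list shares genes with the cytokine, interferon gamma and antimicrobial lists, CXCL1 and IDO1 among them. CHI3L1, CXCL1 and IDO1 rose, and 6 when adjusted over the list alone (score 0.81 ± 0.30, permutation adjusted p = 0.0322, camera adjusted p = 0.458 with an estimated correlation). Without GVHD libraries 17 and 18 that score missed the threshold (0.76 ± 0.32, permutation adjusted p = 0.0602).

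Of 15 goblet cell genes, SPINK4 rose and no other passed, the 1 call also when adjusted over the list alone. The list's median difference was -0.64, camera called it lower (adjusted p = 0.00157; adjusted p = 0.458 with an estimated correlation), and its score difference of -0.44 ± 0.35 did not pass (permutation adjusted p = 0.319). That difference was -0.07 ± 0.26 without GVHD libraries 17 and 18 and 0.13 ± 0.22 with the pan-epithelial covariate. Of 10 enteroendocrine genes, the hormone genes PYY (-1.29 ± 0.36) and GCG (-1.27 ± 0.38) and SCGN fell, and 4 when adjusted over the list alone. The enteroendocrine score difference was -0.60 ± 0.25 (permutation adjusted p = 0.0525; adjusted p = 0.355 with an estimated correlation). In the crypt stem list of 11 genes, PROM1 fell and CD44 rose, the same numbers as when adjusted over the list alone (score -0.15 ± 0.18, permutation adjusted p = 0.547; adjusted p = 0.497 with an estimated correlation). Without the same 2 libraries the crypt stem score difference turned to 0.07 ± 0.10, with a permutation adjusted p = 0.602. Of 16 proliferation genes, 4 rose (CCNA2, BIRC5, CCNB1 and RRM2), and 14 when adjusted over the list alone, with a score difference of 0.60 ± 0.20 (permutation adjusted p = 0.0227; adjusted p = 0.373 with an estimated correlation). Of 14 p53 and apoptosis genes, TNFRSF10B, a death receptor gene, rose by 0.45 ± 0.15, and 4 when adjusted over the list alone (score 0.24 ± 0.08, permutation adjusted p = 0.00844; adjusted p = 0.373 with an estimated correlation).

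Of 12 glucocorticoid response genes, 6 rose, also 6 when adjusted over the list alone. FKBP5 differed by 1.20 ± 0.29, TSC22D3 by 1.01 ± 0.22 and ZBTB16 by 1.47 ± 0.36. The score difference was 0.55 ± 0.16 (permutation adjusted p = 0.00893; adjusted p = 0.355 with an estimated correlation). Of 4 genes that mark the distal colon, HOXB13 (-1.19 ± 0.34) and HOXA13 (-0.52 ± 0.16) fell, and 3 when adjusted over the list alone (score -0.76 ± 0.30, permutation adjusted p = 0.043; adjusted p = 0.349 with an estimated correlation). Adjusted over a family of 10 scores and score differences in place of the 37 lists, it missed the threshold (permutation adjusted p = 0.0645). That score difference was -0.51 ± 0.26 without GVHD libraries 17 and 18 (permutation adjusted p = 0.125) and -0.31 ± 0.20 with the pan-epithelial covariate. Of 12 mitochondrially encoded genes, 4 fell, and 11 when adjusted over the list alone (score -0.84 ± 0.30, permutation adjusted p = 0.0288; adjusted p = 0.349 with an estimated correlation), which without those libraries missed the threshold (-0.79 ± 0.32, permutation adjusted p = 0.0551). Their share of summed FPKM was 0.723 ± 0.621% in GVHD and 1.21 ± 0.689% without (permutation adjusted p = 0.118).

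**Figure D2:**
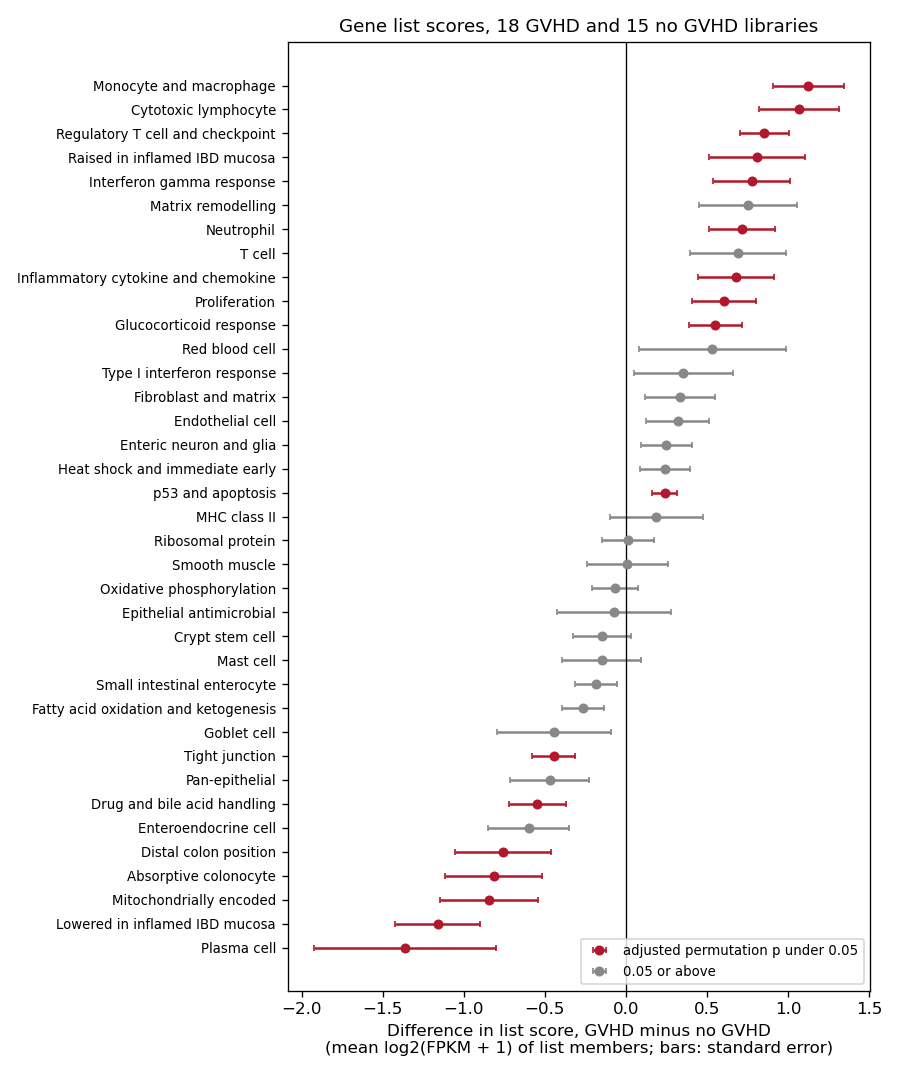
Difference between GVHD (n = 18) and no GVHD (n = 15) libraries in the score of each of 37 gene lists, the mean log2(FPKM + 1) of the tested members, with standard errors as bars. Red points have a permutation adjusted p under 0.05 (17 lists), with monocyte and macrophage genes highest at 1.13 and plasma cell genes lowest at -1.36.

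**Figure D3:**
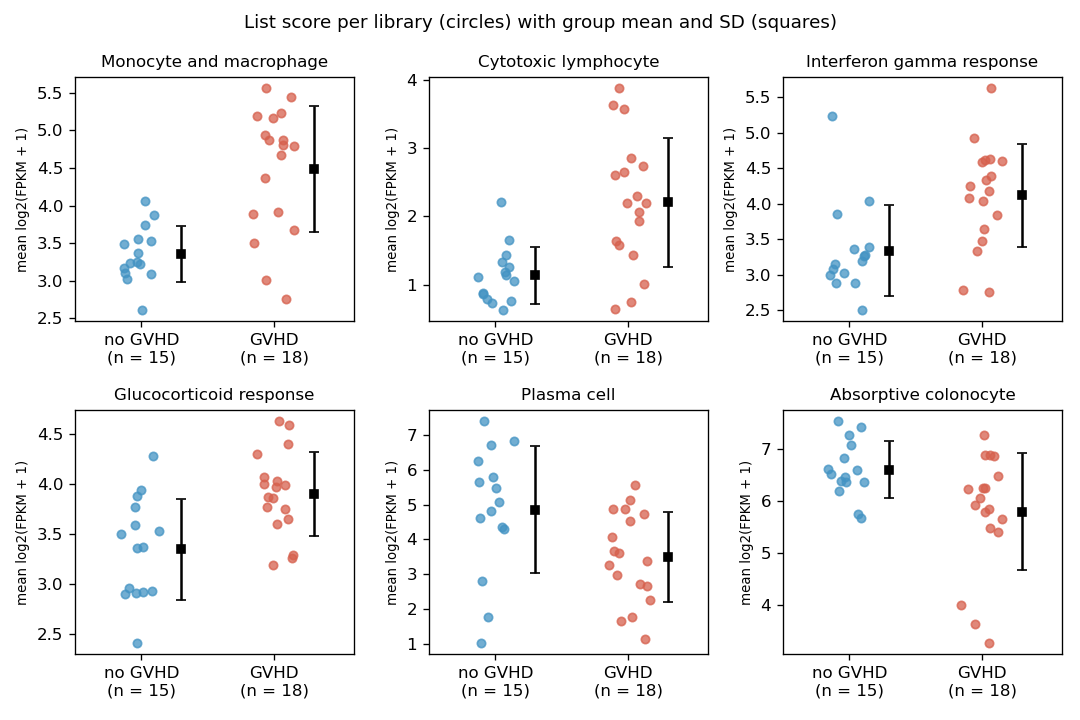
List score of each library (circles, mean log2(FPKM + 1) of the list members) in 6 lists, with the group mean and SD (squares), for 15 no GVHD and 18 GVHD libraries. The groups overlap in every list shown, and the macrophage score averages 4.48 ± 0.836 in GVHD and 3.36 ± 0.367 without.

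The remaining lists did not pass the score test. Matrix remodelling came nearest (0.76 ± 0.30, permutation adjusted p = 0.0501; adjusted p = 0.497 with an estimated correlation), with TIMP1 and TNC among the genes that were higher, and 5 genes higher when adjusted over the list alone. The fatty acid oxidation and ketogenesis score differed by -0.26 ± 0.13 (permutation adjusted p = 0.103; adjusted p = 0.373 with an estimated correlation), with PPARGC1A lower, the 1 call also when adjusted over the list alone. PDGFRA and COL6A3 rose in the fibroblast list and CDH19 and S100B in the neuron and glia list, MYLK fell in smooth muscle and ALPI in the small intestinal list, and HSPA6 and HSPH1 rose in the heat shock list. The counts adjusted over the list alone were 2, 2, 1, 2 and 2. No endothelial, mast cell, red blood cell, oxidative phosphorylation, ribosomal or epithelial antimicrobial gene passed. These 11 lists had score differences between -0.18 ± 0.13 (small intestinal) and 0.53 ± 0.45 (red blood cell). The B cell, eosinophil, Paneth cell and squamous lists had fewer than 3 tested members and were not tested.

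Camera called 24 of the 37 lists, 12 higher and 12 lower, and with an estimated correlation 0 passed. Fry called 15, without absorptive colonocyte (adjusted p = 0.0502) and plasma cell genes (adjusted p = 0.0608). The 66.3% share of calls that were higher fell to 50.5% with quantile normalization, 54.3% without immunoglobulin, haemoglobin and mitochondrial genes, 45.1% with median-of-ratios scaling and 42.9% with limma voom on recovered reads, and rose to 74.4% as TPM. The number of calls, 1653, fell to 127 with the distal colon position score as covariate (93 higher and 34 lower), and rose to 2704 without GVHD library 9.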

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

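The alternatives with recovered reads, without 2 GVHD libraries, with the mitochondrial share or distal position score as covariate, and with the omission and pan-epithelial covariate together were chosen after seeing the data. No paired analysis was possible because the labels give no pairing. Against 1096 genes higher and 557 lower, 103 and 91 by 2-fold or more, with no filter 498 were higher and 276 lower (46 lower by 2-fold), where 40565 genes were tested. Median-of-ratios scaling gave 648 higher, leaving out immunoglobulin, haemoglobin and mitochondrial genes 678, and array weights 1714. Limma voom on recovered reads gave 620 higher, and 159 higher and 225 lower by 2-fold. The mitochondrial covariate gave 497 higher and 256 lower (28 lower by 2-fold). The distal position covariate gave 93 higher and 34 lower (26 and 7 by 2-fold), of which 124 were calls of the reported comparison. The pan-epithelial covariate gave 318 lower, and 68 higher and 32 lower by 2-fold, and with the 2 GVHD libraries also left out 364 lower, 65 and 30. Leaving out those 2 libraries alone gave 49 lower by 2-fold, and 12 of the 17 lists past the score test still passed. Pseudocount 0.1 gave 202 and 145 by 2-fold, and TPM 186 higher by 2-fold. Except where the construction shows it, the cause was not tested. Leaving out each library gave 733 to 1819 higher, 416 to 885 lower, 87 to 152 higher by 2-fold and 64 to 126 lower by 2-fold. Each highest value came without GVHD library 9, the only library to move a count of calls by over 1.5 times. Of the named genes, 70 lost their call with the distal position covariate, 37 with the mitochondrial covariate, 36 with no filter and 30 with the pan-epithelial covariate. Among the 24 genes with the largest differences, only IGHG3 (highest adjusted p = 0.0629) and NXPE4 (0.0546) lost their call when some single libraries were left out. Among the smaller list members named, CD44, CLDN4, ELF3, HOXA13, IDO1, OCLN, PROM1, SCGN, TNC and TNFRSF10B also did. Over all alternatives, more of the 24 lost their call in some setting. Among the falls these were CDHR1 (highest limma adjusted p = 0.0764), PCK1 (0.0922), SLC26A2 (0.109), CKB (0.125), CD177 (0.082), NXPE1 (0.31), NXPE4 (0.354), C21orf88 (0.11) and IGHG3 (0.166). Among the rises they were KIAA1199 (0.277), NRG1 (0.228), SPINK4 (0.108), CHI3L1 (0.0524) and CD8A (0.0524). Depth limits low genes: 1 FPKM for a gene of 1 kb is 12.2 reads in the shallowest library.

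No named gene past the threshold changed sign under any alternative. Of the lists that camera called, the median difference changed sign in 3 that then lost the call: pan-epithelial (0.011) with the distal position covariate, fatty acid oxidation and ketogenesis (0.05 with that covariate, 0.025 with the mitochondrial one) and crypt stem cell (0.041 with the distal position and 0.008 with the pan-epithelial covariate). Among genes and lists that missed it, the direction reversed with the distal position covariate for gene TPSAB1 (0.024), gene GATA2 (-0.08), gene WFDC2 (0.035), gene NOD2 (-0.024), gene COX4I1 (0.019), gene NDUFV1 (0.054), gene COX5A (0.088), gene NDUFA1 (0.079), gene PRAC1 (0.029), gene HOXD13 (0.543) and gene RPS18 (0.004). In that setting the lists that reversed, by the direction of camera and with their median difference, were type I interferon response (0.077), endothelial cell (-0.056), fibroblast and matrix (0.042), oxidative phosphorylation (0.2, adjusted p = 0.0114), enteric neuron and glia (0) and ribosomal protein (0.153). With the pan-epithelial covariate these were gene GATA2 (-0.102), gene COX5A (0.028), gene NDUFA1 (0.003), gene HOXD13 (0.057), endothelial cell (-0.015), fibroblast and matrix (-0.023), oxidative phosphorylation (0.119), enteric neuron and glia (-0.012) and ribosomal protein (0.062). With the 2 libraries also left out they were gene GATA2 (-0.091), gene NOD2 (-0.008), gene COX5A (0.048), gene NDUFA1 (0.051), gene HOXD13 (0.097), endothelial cell (0.028), epithelial antimicrobial (-0.008), oxidative phosphorylation (0.143), enteric neuron and glia (0.006) and ribosomal protein (0.096). Without the 2 libraries alone they were gene GATA2 (-0.038) and endothelial cell (0.025). With the mitochondrial covariate they were gene GATA2 (-0.036), gene COX5A (0.01), gene NDUFA1 (0.036), epithelial antimicrobial (0.192), oxidative phosphorylation (0.1) and ribosomal protein (0.069). With no filter the epithelial antimicrobial list reversed (0.11), and the ribosomal protein list with quantile normalization (0.083), with fry (-0.014) and without no GVHD library 9 (range -0.066 to 0.064 over single omissions). PRAC1 and HOXD13 belong to the distal position list, whose score was the covariate in the first of these settings. The genes of that list cannot all stay lower under it, so a reversal among them there is built in. The cause of the other reversals was not tested.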

Other observations

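The tests of normalization, epithelial share, stromal comparison and the 2 libraries that stood apart were chosen only after the result was seen, as were the genes in this paragraph, taken from those with the smallest p. NNMT, a nicotinamide methyltransferase, was higher in GVHD by 1.70 ± 0.27 on the log2 scale (limma adjusted p = 0.000565). APOD, an apolipoprotein, was higher by 1.34 ± 0.21, SH3PXD2B by 1.22 ± 0.20, and the chemokine gene CCL13 by 1.62 ± 0.27. HK3, a hexokinase of myeloid cells, was higher by 1.31 ± 0.24 and LILRA5, a leukocyte receptor, by 1.62 ± 0.29. All 18 GVHD libraries lay above the no GVHD median for each of these 6 genes. Other genes ranked among them by p, such as ME1 at 17 of 18, are not listed here. The counts in this paragraph therefore add no separate support. ADORA3, an adenosine receptor, was higher by 1.33 ± 0.22 in 17 of 18. BHLHE41, a transcriptional repressor of the circadian clock, differed by -0.92 ± 0.15, ADAMTSL1 by -0.80 ± 0.14 and LGALS9B by -1.52 ± 0.27, with all 18 GVHD libraries below that median. LGALS9B has near-identical relatives, so its reads are uncertain. All 10 stayed past the threshold in every alternative that tested them, including the distal position covariate. They were taken for their small p and the alternatives refit the same libraries, so this adds no separate support either.

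Other splits of the 33 libraries into 18 and 15 gave fewer calls. The real split, 1 of 100, had 1096 genes higher against at most 809 in any other, 557 lower against 384, and 103 and 91 by 2-fold against 58 and 24. This argues against chance assignment but cannot exclude it, since 1 of 100 is the smallest share these splits can give. For gene lists under camera the margin was small, with 24 lists against at most 23 and a median of 15, so that test calls many lists in splits of no meaning.

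More genes were called higher than lower in GVHD (66.3%). Total-read normalization with a few abundant genes taking part of the total may contribute: with immunoglobulin, haemoglobin and mitochondrial genes out of the total 54.3% of calls were higher, against 74.4% as TPM, which scales to the same sum. Scalings that centre the genes push the balance of calls toward equality whatever the cause and do not bear on this. No biological explanation was tested.

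The absorptive colonocyte score was lower in GVHD, with 5 of 17 genes past the threshold and an adjusted p = 0.349 for the list with an estimated correlation. Neither the 2 GVHD libraries that stand apart (-0.523 ± 0.243 without them, permutation adjusted p = 0.0804) nor a lower share of epithelium alone can be excluded. The colonocyte minus pan-epithelial score differed by -0.345 ± 0.162 (permutation adjusted p = 0.096 over 10 scores). Without the 2 GVHD libraries this difference was -0.344 ± 0.172, so they did not set its size, though no permutation test was run on it. Both -0.523 and -0.345 were past the bound of 2 standard errors first set. The requirement that the adjusted p also pass was added after they were seen. Biopsies from a more proximal colon also stay open: with the pan-epithelial covariate the distal position score differed by -0.307 ± 0.204, and the proximal score, lower by -0.06 ± 0.025, met the bound set against this explanation but is void because all 5 of its genes stayed under FPKM 1 in every library. With the distal position covariate the colonocyte score difference shrank from -0.815 to -0.306 ± 0.266 while the macrophage difference stayed at 0.955 ± 0.246, and calls fell to 127, so biopsy site and GVHD itself both stay open. The pan-epithelial covariate gave a colonocyte difference of -0.315 ± 0.173 and a macrophage difference of 0.985 ± 0.235. The shrinkage of the colonocyte difference was therefore not particular to the position score. The fall in calls was much larger with the position score, to 127, against 1056 calls with the pan-epithelial covariate.

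The macrophage score was higher in GVHD, with 11 of 13 genes past the threshold and an adjusted p = 0.335 for the list with an estimated correlation. The tables argue that this is neither a lower share of epithelium raising every other cell type alike (macrophage minus stromal score 0.905 ± 0.236) nor the 2 libraries that stand apart (1.035 ± 0.236 without them). Glucocorticoid exposure of the biopsied tissue stays open and may contribute: within the 18 GVHD libraries the glucocorticoid and macrophage scores correlated (Pearson r = 0.621, permutation p = 0.00605, adjusted p = 0.0363 over 6 relations; Spearman rho = 0.631, permutation p = 0.00602, adjusted p = 0.0361), and r was 0.478 without the 2 libraries farthest on the glucocorticoid score. Within the 15 no GVHD libraries r was 0.381 (permutation p = 0.162, adjusted p = 0.456) and rho 0.429 (permutation p = 0.113, adjusted p = 0.227). The labels give no treatment with steroids, and macrophage accumulation in GVHD is the biological alternative, which these tests do not separate from it.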
